A study of Mus musculus with 19 samples.

How the data were processed

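Mouse quadriceps muscle (C57BL/6) was measured by single-cell RNA sequencing after surgery with extracellular matrix (ECM), polycaprolactone (PCL, a synthetic polyester) or saline, and in animals labelled naive. The 19 libraries are of 3 kinds, named here by sort, age, harvest time and the material on their label. Cells enriched for the leukocyte antigen CD45 came from mice labelled 6 weeks (young) or 104 weeks (old) of age, harvested at 1 week, with 1 library for each of the 4 materials at each age. Sorted fibroblasts (negative for CD45, CD19 and CD31, positive for CD29) came from young mice at 1 or 6 weeks, with 1 library for each of the 4 materials at each time. Sorted macrophages came from young mice at 1 week, with 1 library each for ECM, PCL and saline. Cell barcodes of the first 2 kinds have 12 bases and those of the macrophage sort have 16 bases, so that sort and platform go together. Every condition has 1 library. No paired analysis was possible because every library carries replicate number 1 and no label ties libraries to the same animal.

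The deposited files hold UMI counts (unnormalised counts of unique molecular identifiers) per gene and cell barcode. The values are whole numbers. Per the labels, Cell Ranger, STAR and Seurat were used by the authors, with no versions or order, and the genome build is not given in the sources used here. Cells and genes were already filtered: each sort has its own gene set (16367 genes in the CD45-enriched, 17699 in the fibroblast and 13242 in the macrophage-sort tables). The tables hold 43593 barcodes, against 42156 cells in the design text, and a mean of 1141.6 genes per cell against 1167 in that text. All barcodes were kept.

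Depth differed between sorts. Library totals ran from 885161 UMIs (young CD45-enriched library labelled ECM) to 14586276 UMIs (macrophage-sort library labelled ECM). Median UMIs per cell ran from 684 to 1215 in the CD45-enriched libraries, from 1767 to 4111.5 in the fibroblast sort and from 4594 to 5662 in the macrophage sort. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals, and counts and ratios of counts in single libraries carry exact Poisson 95% intervals. These intervals cover counting error only, not differences between animals. Where a count was 0, the limit is what 3 counts over the group would give.

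Cells of each sort were clustered separately with scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Counts per cell were scaled to 10000 and log-transformed. The clustering used 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1. It gave 19 clusters in the CD45-enriched, 17 in the fibroblast and 11 in the macrophage-sort cells. A cluster took the name of the cell type whose marker genes, from lists written before the data were examined, were highest in it on average across all clusters. It stayed unnamed if fewer than 3 of these markers were found in at least 10% of its cells, if its 10 leading genes held more markers of another type, or if its cells were shallow and none of the 10 was a marker of its own type. Names end in "-like" because no protein was measured. The separate T cell and NK cell types were merged into 1 class after the clusters were seen. A further naming rule, which left 2 macrophage-sort clusters unnamed, was removed after the clusters were seen and before any test. Scrublet, run per library, called 0.18% of cells, which is too few for a working doublet threshold, so no doublets were removed.

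For the tests, UMIs were summed per library over macrophage-like cells (CD45-enriched libraries) or fibroblast-like cells (fibroblast sort). A quasi-likelihood F test in edgeR 4.0.16 (R 4.3.3) was fitted to the 8 libraries of each kind, with TMM factors and the default filter on low counts. The model had a term for material and a term for age (macrophage-like cells) or harvest time (fibroblasts). With 8 libraries and 3 residual degrees of freedom, a gene's own error is the part of its values that these additive terms leave over. The test thus asks for a material effect alike at both ages or times. That effect cannot be separated from differences between animals that the material labels share. edgeR also shares error between genes, with a median prior of 40.7 degrees of freedom in macrophage-like cells and 4.15 in fibroblasts. Error in macrophage-like cells thus rests mostly on other genes, and counts of passing genes are not comparable between the cell types. P-values were adjusted by Benjamini and Hochberg with a threshold of 0.05 over all tested genes of a comparison. There were 10 comparisons: PCL against saline, ECM against saline, PCL against ECM and saline against naive in each cell type, old against young in macrophage-like cells, and 6 weeks against 1 week in fibroblasts. Fold changes are log2. Their standard error (SE) is approximate, taken as the absolute fold over the square root of the F statistic. Levels in these comparisons are CPM (counts scaled to a TMM-adjusted library total of 1e6) as a mean over the libraries of an arm. Figures of gene levels, the macrophage sort and cytokine counts use the total of the summed cells without TMM factors.

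Gene lists for macrophages and fibroblasts were fixed before the data were examined and tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison. They were tested again with a correlation estimated per list. Of the 125 list tests, those that passed did so only with the preset correlation. The smallest adjusted p with an estimated correlation was 0.0618. Lists of alternative activation, inflammatory, interferon response, lipid handling and foreign-body macrophage, tissue-resident, antigen presentation class II, complement and scavenging, blood monocyte, glycolysis and hypoxia, cell cycle, dissociation and early response, and haemoglobin genes were used in macrophage-like cells. Lists of fibrillar collagen and matrix, basement membrane, contractile myofibroblast, adventitial progenitor, resident perimuscular and adipogenic, interleukin-17 and inflammatory response, interferon response, TGF-beta targets, tendon and cartilage, senescence and p53, cell cycle, dissociation and early response, and haemoglobin genes were used in fibroblasts. Some members, such as C1qc, Ccr2 or Dcn, are also markers used to name the classes. T helper cytokines were fixed as a list to be read as counts and were not tested.

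The genes named follow a rule written before the data were examined. In a tested comparison they are the 8 largest rises and 8 largest falls among genes past the threshold, with the same sign at both ages or times (or in at least 3 of the 4 materials) and at least 50 CPM in the higher arm, plus up to 4 passing members of each list. Where fewer than 5 genes passed, list members with a 2-fold change of the same sign at both times and at least 50 CPM in the higher arm are named, at most 3 per list, and said not to have passed. Mitochondrial, ribosomal protein, haemoglobin and sex-linked genes and predicted gene models were left out of the ranking by fold. The macrophage-sort libraries have no replicate, so ratios of CPM are given without a test. Genes there are the 8 highest and 8 lowest ratios for each pair among genes with at least 50 CPM in the higher library and at least 20 UMIs over the pair, plus up to 3 members of each list. List medians in that sort were placed among 10000 random lists matched in expression over 20 bins.

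The edgeR procedure was tested on simulated counts with 200 changed genes and the library totals of the data. All libraries shared a mean profile, and each gene had the spread fitted to genes of like expression. Spread particular to a gene and differences of a material between ages or times were not simulated. The shares recovered can therefore overstate recovery in the data. It recovered 29% of 2-fold and 93% of 4-fold changes in PCL against saline in macrophage-like cells, and 35% and 95% in fibroblasts. For age it recovered 59% and 100%, and for harvest time 79% and 98%. False calls were between 1.12% and 4.22% of calls.

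Alternatives planned before the data were examined were DESeq2 1.42.0 in place of edgeR, RLE factors, no filter on low counts, leaving out each library in turn, no block, removal of cells called by scrublet, cells with at least 500 genes, clusters at resolution 2, all cells summed, mitochondrial, ribosomal protein and haemoglobin genes left out, and the macrophage-sort libraries added as a further block. For the ratios in the macrophage sort they were a minimum of 20 CPM, TMM factors and all cells summed. Added after the data were seen were leaving out the 5% of cells with the highest scrublet score, adding monocyte-like cells, and leaving out the 1-week fibroblast libraries labelled saline and naive. Profiles of libraries were compared by Pearson correlation across genes of at least 20 CPM, with intervals from 2000 bootstrap draws over genes, which are not independent replicates. Figures were drawn with matplotlib 3.10.9.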

Results

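The CD45-enriched libraries held 21486 cells, the fibroblast sort 17733 cells and the macrophage sort 4374 cells. Materials below are those on the labels, and each combination of sort, age, time and material is 1 library, so no value has a replicate of its own. A possible wrong assignment of material labels to the CD45-enriched libraries, taken up below, bears on the contrasts of materials in macrophage-like cells.

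Macrophage-like cells were the largest named class in 5 of the 8 CD45-enriched libraries, and their share differed by labelled material and by age. In young mice they made up 65.6% of cells in the library labelled naive (95% interval 64.2 to 67.0), 39.6% in PCL, 35.6% in saline and 8.19% in ECM (6.48 to 10.2, 74 cells). In old mice the shares were 39.5% in naive, 29.6% in PCL, 43.6% in saline and 26.0% in ECM. Neutrophil-like cells were 14.5% (young) and 8.11% (old) of the libraries labelled saline, and 0.10% to 0.95% of the others. Monocyte-like cells followed, at 15.2% and 13.9% in saline and from 0.66% to 6.96% elsewhere. Fibroblast-like cells were 45.8% of the young library labelled ECM, which also held 14.7% endothelial-like and 12.2% erythroid-like cells, and 8.07% of the young library labelled naive. T or NK cell-like cells were 11.1% and 10.7% in naive (young and old), 11.2% in young PCL and 3.76% to 5.73% in the others. Unnamed cells were 3.64% to 10.7% of these libraries. Most were in a cluster of 941 cells led by Igkc, Rgs5, Ighm, Fabp4 and Acta2. It was closest to B cells, and no B cell-like class was named. The others were a cluster of 244 cells led by Top2a and Mki67, closest to macrophages, so that dividing cells are partly missing from the macrophage-like sums. In the fibroblast sort, 80.9% to 91.6% of cells were fibroblast-like and none was unnamed. In the macrophage sort, macrophage-like cells were 99.2% (ECM), 96.0% (PCL) and 93.8% (saline), and 0.79%, 1.60% and 6.16% were unnamed. These shares also reflect enrichment and recovery and were not tested.

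Different clusters held the macrophage-like cells of different labels. The cluster led by Spp1 and Cxcl3 held 29.1% (young) and 37.1% (old) of all cells in the saline libraries and 0.44% to 2.74% elsewhere. A cluster led by Retnla and Ear2, an eosinophil-type ribonuclease gene, held 13.8% to 17.7% in naive, PCL and old ECM, 4.09% in young ECM and 1.15% to 1.42% in saline. The cluster of Apoe and complement C1q genes was at 29.5% in young naive, and that of Gpnmb and Mmp12, an elastase, at 12.1% in young naive and 0 in ECM. The fibroblast sort was as uneven by cluster. Cells with Spp1, Cxcl5 and Timp1 in the lead were 45.0% of 1-week PCL and 26.0% of 1-week ECM, and the cluster led by Saa3 was 23.8% of 6-week PCL. Over genes, the 1-week fibroblasts labelled saline had a correlation of 0.968 with 6-week naive and 0.889 with 1-week ECM, and those labelled naive 0.89 and 0.971.

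Macrophage-like cells labelled PCL had 9 of 12 class II genes and 6 of 17 alternative activation genes higher than those labelled saline. The median of the alternative activation list was 0.02 in young and 1.04 in old mice, a difference that was not tested. Retnla, a secreted marker of alternative activation, rose by 3.97 log2 units (SE 0.37, adjusted p = 9.83e-11), from 803 to 12600 CPM. Cd163, a haemoglobin scavenger receptor of resident macrophages, rose by 3.77 (adjusted p = 1.25e-07), and Mgl2, a lectin of alternatively activated cells, by 2.84. Of the 12 class II genes 9 rose, with H2-Ab1 up by 1.61 (adjusted p = 0.000419) and their activator Ciita by 2.21. The sums pool clusters whose shares differ between labels, so folds here and below do not separate cell mixture from change within cells. The cluster led by Retnla and Ear2 also has H2-Ab1 among its leading genes. Its 10 leading genes held 1 macrophage marker and 1 marker of another type. Spp1, the osteopontin of foreign-body and scar macrophages, fell by 3.94 (SE 0.32, adjusted p = 2.12e-12), as did the bone-resorbing protease Ctsk (-3.65) and the neutrophil attractant Cxcl3 (-4.64). Arg1, an arginine-consuming enzyme also counted as alternative activation, fell by 1.86 (adjusted p = 0.0362), a fit over log2 ratios of -0.7 in young and -5.38 in old mice. In edgeR, 276 genes were higher and 260 lower of 10123 tested, 1790 had an unadjusted p under 0.05, and DESeq2 called 313. Nearly all calls were lost with no block for age, with all cells summed or with the macrophage-sort libraries added as a block, as given below. Of the 536, 533 had the same sign at both ages. The fit takes disagreement between ages as error, so genes that pass tend to agree. Such counts, here and in the other comparisons, are therefore not a separate check. The median over all genes was 0.04, and 12.8% of genes differed at least 2-fold.

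Several gene lists moved in that comparison. Class II genes had 9 higher and 0 lower of 12 (9 and 0 adjusted over the list alone, camera adjusted p = 4.98e-09; adjusted p = 0.221 with an estimated correlation). Lipid handling and foreign-body genes had 0 higher and 12 lower of 27 (2 and 14 adjusted over the list alone, adjusted p = 6.53e-19; adjusted p = 0.17 with an estimated correlation). Blood monocyte genes had 2 higher and 7 lower of 15 (2 and 12 adjusted over the list alone, adjusted p = 1.94e-09; adjusted p = 0.17 with an estimated correlation), among them Ly6c2, the surface marker of inflammatory monocytes, at -2.38. Alternative activation genes had 6 higher and 2 lower of 17 (7 and 4 adjusted over the list alone, adjusted p = 4.44e-05; adjusted p = 0.17 with an estimated correlation), and tissue-resident genes 7 and 2 of 18 (13 and 2 adjusted over the list alone, adjusted p = 1.56e-05; adjusted p = 0.18 with an estimated correlation). The chemokine Ccl8 of the latter list was 2.24 higher (adjusted p = 0.00214), but -0.14 without the young library labelled PCL. Glycolysis genes leaned down (0 higher and 5 lower of 23; 1 and 11 adjusted over the list alone; adjusted p = 3.87e-07; adjusted p = 0.221 with an estimated correlation), with the glycolytic enzyme Pkm at -1.28. Early-response genes leaned up (6 and 0 of 23; 7 and 0 adjusted over the list alone; adjusted p = 0.000237; adjusted p = 0.221 with an estimated correlation). The inflammatory list leaned down (2 and 5 of 23; 2 and 6 adjusted over the list alone; adjusted p = 0.000878; adjusted p = 0.351 with an estimated correlation), although the cytokine gene Il6 rose by 2.62. The interferon list had 0 and 1 of 24 called (0 and 1 adjusted over the list alone, adjusted p = 0.00113 downward; adjusted p = 0.542 with an estimated correlation), and the haemoglobin list 0 of 4 (0 and 2 adjusted over the list alone, adjusted p = 0.0164 downward; adjusted p = 0.346 with an estimated correlation). Complement (1 and 1 of 14, adjusted p = 0.696) and cell cycle (1 and 0 of 25, adjusted p = 0.187, without the unnamed Top2a and Mki67 cluster) did not pass. Neutrophil granule genes such as Ngp and Camp, at least 48.9-fold and 42.4-fold lower against 3 counts over the PCL group, went with the neutrophil-like share of the saline libraries. For this pair, macrophage-sort list medians were opposite in sign to both ages for class II (-1.22), tissue-resident (-0.99) and blood monocyte genes (1.42). That held also for glycolysis (1.41), lipid handling (0.34), early-response (-0.62), inflammatory (0.19) and alternative activation genes (-0.14). Interferon genes (0.02) were alike in young mice only and cell cycle genes (-0.56) in old mice only. Complement genes (-0.64) were opposite in young mice, with -0.0 in old mice. Leaving out the old saline, young PCL or young saline library gave 246, 281 or 232 genes.

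Against saline, macrophage-like cells labelled ECM had 10 of 18 resident genes higher and 22 of 27 foreign-body genes lower. Over all cells, mitochondrial genes held 7.25% (young) and 7.01% (old) of UMIs in ECM. The other CD45-enriched libraries had 1.48% to 4.67%. The ECM libraries also held the fewest cells (904 and 1049), so cell quality and material cannot be told apart in the ECM contrasts. Retnla rose by 4.91 (SE 0.38, adjusted p = 9.69e-13), from 803 to 24100 CPM. Cd163 rose by 5.47, Lyve1, the hyaluronan receptor of vessel-associated resident macrophages, by 4.21 (adjusted p = 8.27e-10), and the lectin gene Cd209f by 6.94 (adjusted p = 9.69e-13). Its neighbour Cd209g had 67 UMIs in ECM and 2 in saline, a ratio of 222 (95% counting interval 59.2 to 1870). Spp1 fell by 8.28 (SE 0.46, adjusted p = 7.78e-18), to 19.8 from 6550 CPM, and Arg1 by 6.68 (adjusted p = 4.45e-07, 4 UMIs in ECM). With 1 or 2 UMIs in the ECM libraries, the saline level was 334 times that of ECM for Ctsk (59.9 to 13200), 255 times for the osteoclast phosphatase Acp5 (45.7 to 10100) and 121 times for the lysosomal glycoprotein gene Gpnmb (33.5 to 1000). Hp, the haemoglobin-binding haptoglobin of monocytes and neutrophils, was at least 25.1-fold lower (0 UMIs, 3 counts over the group). In all, 407 genes were higher and 551 lower, 2385 had an unadjusted p under 0.05, DESeq2 called 764, and 941 of the 958 had the same sign at both ages. The count was far lower with no block for age, with all cells summed or with the macrophage-sort libraries added, as given below. For this pair, macrophage-sort list medians were opposite in sign for lipid handling (0.47), glycolysis (1.71), class II (-2.02), early-response (-0.76) and tissue-resident genes (-0.15). Signs were alike for alternative activation, inflammatory, complement, cell cycle and blood monocyte genes, and for interferon genes in young mice only.

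Lipid handling and foreign-body genes had 0 higher and 22 lower of 27 in ECM (0 and 24 adjusted over the list alone, adjusted p = 7.8e-48; adjusted p = 0.0632 with an estimated correlation). Glycolysis and hypoxia genes had 1 higher and 17 lower of 23 (1 and 18 adjusted over the list alone, adjusted p = 2.84e-14; adjusted p = 0.0632 with an estimated correlation). In that list the cytokine-like Mif fell by 2.67 and the glucose transporter gene Slc2a1, at 1 UMI in ECM, was 30.3 times higher in saline (5.37 to 1200). Tissue-resident genes had 10 higher and 2 lower of 18 (11 and 3 adjusted over the list alone, adjusted p = 4.86e-11; adjusted p = 0.0632 with an estimated correlation). Alternative activation genes split, 7 and 4 of 17 (8 and 4 adjusted over the list alone, adjusted p = 0.000488; adjusted p = 0.0632 with an estimated correlation). Class II genes had 8 higher and 1 lower of 12 (10 and 1 adjusted over the list alone, adjusted p = 2.8e-06; adjusted p = 0.213 with an estimated correlation), the fall being Ctss, the protease that clears the invariant chain (-2.14). Blood monocyte genes had 2 and 8 of 15 (2 and 9 adjusted over the list alone, adjusted p = 0.000121; adjusted p = 0.119 with an estimated correlation), and inflammatory genes 3 and 7 of 23 (3 and 10 adjusted over the list alone, adjusted p = 0.000438; adjusted p = 0.284 with an estimated correlation). Early-response genes had 10 and 0 of 23 (13 and 1 adjusted over the list alone, adjusted p = 8.07e-10; adjusted p = 0.0632 with an estimated correlation). Haemoglobin genes had 4 and 0 of 4 (4 and 0 adjusted over the list alone, adjusted p = 4.44e-12; adjusted p = 0.0632 with an estimated correlation), beside the erythroid-like share of 12.2% and 4.58% in the ECM libraries. The cell cycle list leaned down with 0 and 1 of 25 called (0 and 1 adjusted over the list alone, adjusted p = 0.0391; adjusted p = 0.266 with an estimated correlation), and the complement (2 and 5 of 14, adjusted p = 0.146) and interferon lists (1 and 0 of 24, adjusted p = 0.0907) did not pass. The young ECM library gave 74 macrophage-like cells, and the count was 464 without it, 283 without the old ECM library and 554 without the old saline library.

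Between the 2 materials, 17 of 27 lipid handling and foreign-body genes were higher in macrophage-like cells labelled PCL than in those labelled ECM, while single resident genes differed in both directions. Spp1 was higher in PCL by 4.34 (SE 0.46, adjusted p = 1.09e-08) and Ccl8 by 3.65 (adjusted p = 3.11e-05; log2 6.86 in young and 1.17 in old mice). Arg1 was 4.82 higher (adjusted p = 0.00325), but that fit rests on the young pair, with 1166 UMIs in PCL and 0 in ECM, against 22 and 4 UMIs in old mice (log2 0.9). Gpnmb, at 2 UMIs in ECM, was 130 times higher (35.8 to 1070), and Atp6v0d2, a proton pump subunit of fusing macrophages, 49.0 times (13.5 to 406). Lyve1 fell by 3.25 (adjusted p = 4.16e-07), as did Cd209f (-4.55, adjusted p = 3.08e-09) and Mgl2 (-1.21, adjusted p = 0.0302). In edgeR, 103 genes were higher and 40 lower, 1107 had an unadjusted p under 0.05, DESeq2 called 100, and 136 of the 143 had the same sign at both ages. Most of these calls were lost with no block for age, all cells summed or the macrophage-sort libraries added, as given below. The median over all genes was 0.12 toward PCL.

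Lipid handling and foreign-body genes had 17 higher and 1 lower of 27 in PCL (22 and 1 adjusted over the list alone, adjusted p = 7.96e-43; adjusted p = 0.0641 with an estimated correlation). Glycolysis genes had 5 and 0 of 23 (14 and 0 adjusted over the list alone, adjusted p = 2.61e-10; adjusted p = 0.125 with an estimated correlation), with Mif 2.04 higher. Tissue-resident genes had 2 and 3 of 18 (2 and 6 adjusted over the list alone, adjusted p = 7.54e-07 downward; adjusted p = 0.125 with an estimated correlation). Interferon genes had 0 and 3 of 24 (0 and 11 adjusted over the list alone, adjusted p = 3.42e-09; adjusted p = 0.335 with an estimated correlation), with the interferon-inducible GTPase gene Iigp1 at -2.25. Early-response genes had 0 and 3 of 23 (1 and 5 adjusted over the list alone, adjusted p = 5.8e-06; adjusted p = 0.132 with an estimated correlation), and haemoglobin genes 0 and 4 of 4 (0 and 4 adjusted over the list alone, adjusted p = 4.41e-31; adjusted p = 0.0618 with an estimated correlation). The cell cycle list, with 0 genes called (0 adjusted over the list alone), leaned up in PCL with a median of 0.96 (adjusted p = 0.000116; adjusted p = 0.125 with an estimated correlation), and so did inflammatory genes (2 and 0 of 23; 3 and 0 adjusted over the list alone; adjusted p = 0.0403; adjusted p = 0.529 with an estimated correlation). Alternative activation (2 and 2 of 17, adjusted p = 0.317, median 0.04 against a test that leaned down), class II (1 and 0 of 12, adjusted p = 0.665), complement (0 of 14, adjusted p = 0.0857) and blood monocyte genes (2 and 2 of 15, adjusted p = 0.906) did not pass. Without the old or the young ECM library 24 or 44 genes passed.

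Macrophage-like cells labelled saline had 7 of 12 class II and 7 of 18 resident genes lower than those labelled naive, and 6 of 15 monocyte genes higher. The median of the alternative activation list was -0.03 in young and -0.64 in old mice. Retnla fell by 4.63 (SE 0.38, adjusted p = 3.24e-12), Ccl8 by 3.54 (adjusted p = 1.76e-06), Mgl2 by 3.23, and the mannose receptor gene Mrc1 fell as well (-1.59, adjusted p = 0.00048). The eosinophil-type ribonuclease gene Rnase2a, at 2 UMIs in saline, was 150 times higher in naive (41.3 to 1240). Spp1 rose by 3.32 (SE 0.31, adjusted p = 1.05e-10), the platelet chemokine gene Ppbp by 5.15 (adjusted p = 4.01e-11) and Acp5 by 2.44. In edgeR, 265 genes were higher and 239 lower, 1672 had an unadjusted p under 0.05, DESeq2 called 246, and 500 of the 504 had the same sign at both ages. With no block for age or with all cells summed, most of these calls were lost, as given below.

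Class II genes had 0 higher and 7 lower of 12 in saline (1 and 9 adjusted over the list alone, adjusted p = 6.8e-08; adjusted p = 0.261 with an estimated correlation). Blood monocyte genes had 6 and 1 of 15 (9 and 1 adjusted over the list alone, adjusted p = 1.67e-08; adjusted p = 0.255 with an estimated correlation). Alternative activation genes had 3 and 6 of 17 (3 and 6 adjusted over the list alone, adjusted p = 5.01e-05 downward; adjusted p = 0.218 with an estimated correlation), tissue-resident genes 1 and 7 of 18 (2 and 9 adjusted over the list alone, adjusted p = 0.000343; adjusted p = 0.261 with an estimated correlation) and lipid handling genes 6 and 3 of 27 (8 and 5 adjusted over the list alone, adjusted p = 0.00182 upward; adjusted p = 0.541 with an estimated correlation). Early-response genes had 0 and 2 of 23 (0 and 6 adjusted over the list alone, adjusted p = 9.66e-05; adjusted p = 0.261 with an estimated correlation). Inflammatory genes went both ways (4 and 5 of 23, adjusted p = 0.441), and the interferon (0 and 2, adjusted p = 0.842), complement (0 and 1, adjusted p = 0.164), glycolysis (0 and 2, adjusted p = 0.25), cell cycle (0 and 1, adjusted p = 0.164) and haemoglobin lists (0, adjusted p = 0.155) did not pass. S100a8, an abundant neutrophil protein, rose by 4.42 and went with the neutrophil-like share. Leaving out the old PCL library gave 773 genes, either naive library 225, and the young saline library 161.

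**Figure D1:**
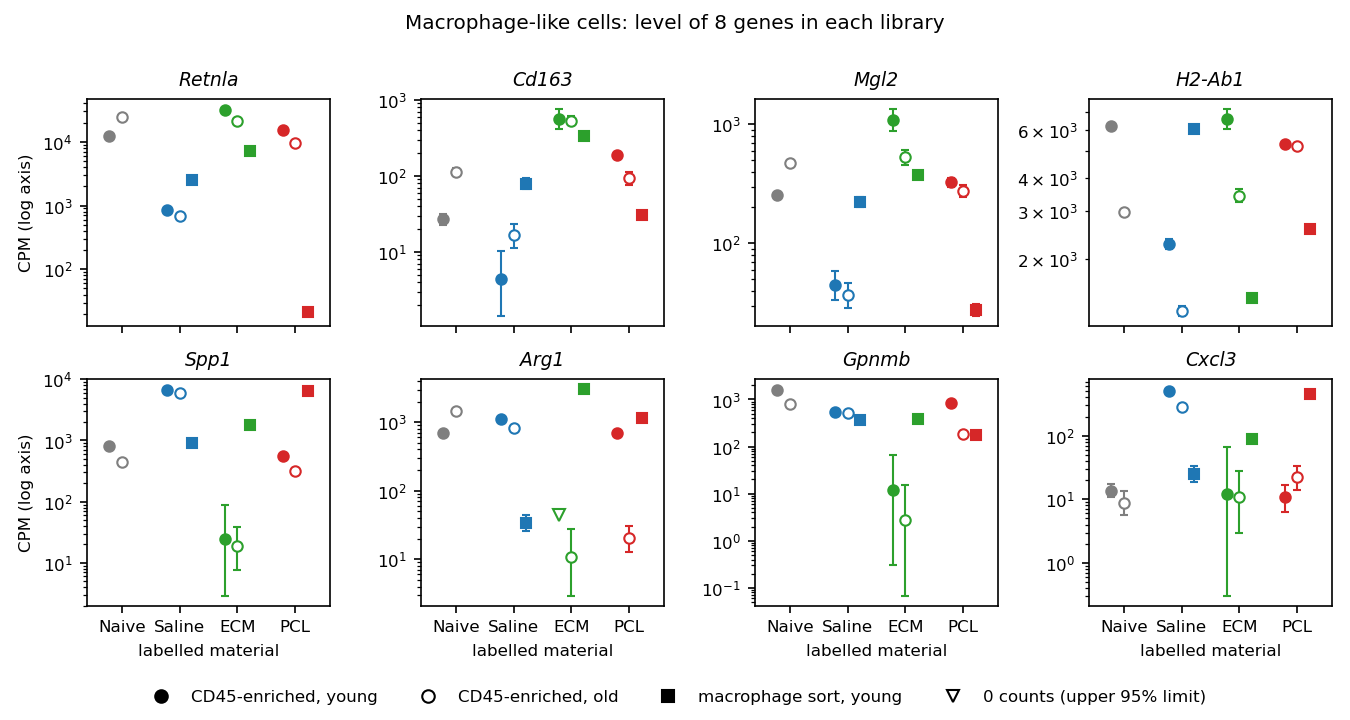
CPM (log axis) of 8 genes in macrophage-like cells by labelled material: filled circles, young CD45-enriched; open circles, old CD45-enriched; squares, young macrophage sort; bars, 95% counting intervals; triangles, upper 95% limits at 0 UMIs. Spp1 is at 6760 (young) and 5860 (old) in CD45-enriched saline and 24.2 and 19.0 in ECM, whereas in the macrophage sort it is at 6530 in PCL and 894 in saline.

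With age, 11 of 23 glycolysis genes fell in macrophage-like cells, and single genes of lipid transport, complement and the interferon response changed. Apoe, the lipid carrier, fell from 12600 to 2310 CPM (log2 -2.5, SE 0.23, adjusted p = 8.1e-11), and the complement component gene C1qc fell by 1.14 (adjusted p = 5.37e-05). Both fell in all 4 materials. Trim30a, an interferon-induced ligase, rose by 1.09 (adjusted p = 0.000202), Mx1, an antiviral GTPase, by 1.19 (adjusted p = 0.0038), the ubiquitin-like Isg15 by 1.02 (adjusted p = 0.00902), and Ccr2, the chemokine receptor of blood monocytes, by 0.82 (adjusted p = 0.0032). Malt1, a protease of NF-kappaB signalling, rose by 1.37 (adjusted p = 4.29e-06), while the early-response gene Junb fell by 1.91 (adjusted p = 1.18e-08). In edgeR, 619 genes were higher and 858 lower, 2886 had an unadjusted p under 0.05, and DESeq2 called 972. Of the 1477, 1466 kept their sign in at least 3 of the 4 materials.

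The interferon list had 6 higher and 0 lower of 24 in old cells (6 and 0 adjusted over the list alone, adjusted p = 0.000148; adjusted p = 0.819 with an estimated correlation). Glycolysis genes had 0 and 11 of 23 (0 and 14 adjusted over the list alone, adjusted p = 2.92e-06; adjusted p = 0.756 with an estimated correlation), with Mif at -1.31. Early-response genes had 1 and 7 of 23 (1 and 11 adjusted over the list alone, adjusted p = 0.00395; adjusted p = 0.756 with an estimated correlation). Haemoglobin genes had 0 and 4 of 4 (0 and 4 adjusted over the list alone, adjusted p = 3.65e-13; adjusted p = 0.247 with an estimated correlation), and the erythroid-like share was higher in young than old mice for every material. Lipid handling genes had 2 and 8 of 27 called (7 and 10 adjusted over the list alone), with Gpnmb at -1.14, but the list did not pass (adjusted p = 0.129). Nor did the blood monocyte (3 and 1 of 15, adjusted p = 0.129), cell cycle (0 and 2 of 25, adjusted p = 0.351), alternative activation (0 and 1 of 17, adjusted p = 0.634), inflammatory (1 and 3 of 23, adjusted p = 0.634), complement (0 and 2 of 14, adjusted p = 0.634), tissue-resident (1 and 2 of 18, adjusted p = 0.652) and class II lists (0 and 1 of 12, adjusted p = 0.788). Without the old naive, old saline, young naive or young saline library the count was 575, 531, 588 or 498.

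In the macrophage sort, where each material is 1 library and a difference has no replicate check, monocyte genes were highest in the library labelled PCL and alternative activation genes in the library labelled ECM. Against saline, PCL had 33.9 times the CPM of Arg1 (26.4 to 44.2), 7.31 times that of Spp1, 17.6 times that of Cxcl3 and 26.2 times that of the monocyte proteoglycan gene Vcan, and 119-fold less Retnla (104 to 137). These 5 directions were opposite to those between PCL and saline in the young and the old CD45-enriched libraries. Against saline, ECM had 88.2 times the Arg1 (68.8 to 115), 10.7 times the eosinophil-attracting chemokine gene Ccl24, 8.77 times the Ccl8 and 4.24 times the Cd163, and at least 174-fold more Rnase2a (0 UMIs in saline, 3 counts as the limit). It had 4.19-fold less H2-Ab1 and 23.0-fold less of the fractalkine receptor gene Cx3cr1. In both CD45-enriched ages Ccl24 and Cd163 went the same way and Arg1, Ccl8 and H2-Ab1 the opposite way. Between materials, PCL had 340-fold less Retnla than ECM (299 to 390), 13.6-fold less Mgl2 and 15.3-fold less Ccl8, with 20.3 times the monocyte gene Ms4a4c. In both CD45-enriched ages Retnla and Mgl2 were also lower in PCL than in ECM, while Ccl8 was higher. Arg1, higher in PCL at both of those ages, was at 1160 CPM in PCL and 3010 CPM in ECM in the macrophage sort. At least 2-fold differences were found for 153 genes higher and 127 lower of 2827 in PCL against saline, 119 and 214 of 2753 in ECM against saline, and 205 and 107 of 2766 in PCL against ECM. With these libraries as a further block beside the CD45-enriched ones, edgeR called 0 of 9757 genes in the 3 comparisons of materials, and 153 (PCL against saline), 705 (ECM against saline) and 328 (PCL against ECM) had an unadjusted p under 0.05.

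List medians in the macrophage sort were set beside random lists of matched expression. Genes of a list can move together while random genes need not, which by itself makes extreme percentiles more likely. The percentiles are therefore not a test of a list, and each material is 1 library. In PCL against saline, the medians of blood monocyte (log2 1.42) and glycolysis genes (1.41) lay above all 10000 random lists, and those of class II (-1.22) and tissue-resident genes (-0.99) below all. Lipid handling genes were at 0.34 (percentile 99.4), complement genes at -0.64 (percentile 0.01), early-response genes at -0.62 (percentile 0), cell cycle genes at -0.56 (percentile 0.32), alternative activation genes at -0.14 (percentile 5.46), inflammatory genes at 0.19 (percentile 69.6) and interferon genes at 0.02 (percentile 32.6). In ECM against saline, glycolysis (1.71), alternative activation (1.15) and lipid handling genes (0.47) lay above all random lists, and class II (-2.02), interferon (-1.29), inflammatory (-1.27) and early-response genes (-0.76) below. In PCL against ECM, blood monocyte (1.89), interferon (1.45) and inflammatory genes (1.18) lay above and alternative activation (-1.32) and tissue-resident genes (-1.02) below. Class II genes were at 0.69 (percentile 99.7), glycolysis genes at -0.30 (percentile 0.09) and lipid handling and foreign-body genes at -0.24 (percentile 3.06) in that pair, where the glycolysis and lipid handling medians in CD45-enriched macrophage-like cells were 0.97 and 1.61. Cell cycle genes were at -0.11 (percentile 18.1) and early-response genes at -0.04 (percentile 24.4). In ECM against saline, cell cycle genes were at -0.37 (percentile 6.7), tissue-resident genes at -0.15 (percentile 10.5) and blood monocyte genes at -0.03 (percentile 33.5). Complement genes were at -0.38 (percentile 1.03) in ECM against saline and -0.20 (percentile 12.8) in PCL against ECM. The PCL library also held 42 neutrophil-like cells, and the other libraries of this sort 0.

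**Figure D2:**
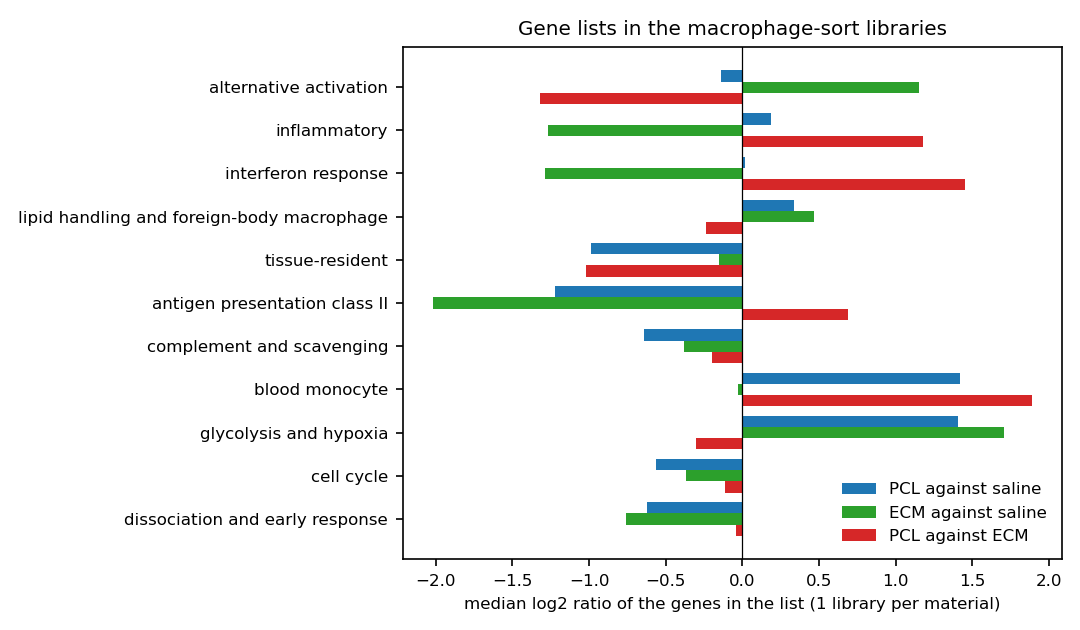
Median log2 ratio of each gene list (horizontal bars) for the 3 pairs of materials in the macrophage sort, 1 library per material, with no error bars. Class II genes are lowest in ECM against saline (-2.02) and blood monocyte genes highest in PCL against ECM (1.89).

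T helper cytokines were read as UMI counts in T or NK cell-like cells of the CD45-enriched libraries. Il17a, Il17f, Il22, Il4, Il21 and Rorc are not in the table of these libraries. Il13, a type 2 cytokine, had 127 UMIs in 5 of 287 cells of the young library labelled PCL (1.74%) and 36 UMIs in 6 of 487 cells of young naive (1.23%), against 0.59% and 0.31% of their macrophage-like cells. It had 0 UMIs in the 106 cells of young saline and the 34 cells of young ECM, at median depths of 482 and 654.5 UMIs, where a cell that expresses the gene can show none. In old mice it had 5 UMIs in naive, 1 in PCL and 0 in the other libraries. Il5, its neighbour that sustains eosinophils, had a UMI in 9 of 55 cells of old ECM (16.4%, 7.77 to 28.8), against 0.37% of macrophage-like cells of that library, with median depths of 653 and 942 UMIs. Ifng, the type 1 cytokine, had a UMI in 13.6% of T or NK cell-like cells of young PCL (9.84 to 18.1), 9.03% of young naive and 10.8% of old saline, against 0.49%, 0.28% and 0.12% of their macrophage-like cells. Median depths were 937, 739 and 466 UMIs in the T or NK cell-like cells and 1205, 1331.5 and 774.5 in the macrophage-like cells.

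Between sorted fibroblasts labelled PCL and saline only 1 gene passed, and it was lower in PCL. Cyp26b1, which degrades retinoic acid, fell by 2.44 (SE 0.18, adjusted p = 0.0287), at 6.1 against 33.3 CPM at 1 week and 6.8 against 37.1 CPM at 6 weeks, and it is named after its values were seen. The acute-phase gene Saa3 was at 1710 against 2.01 CPM (log2 10.10, SE 1.31, adjusted p = 0.058), the neutrophil attractant Cxcl5 at 403 against 1.81 CPM (7.92, adjusted p = 0.0666) and the protease inhibitor gene Timp1 at 1060 against 55.2 CPM (3.82, adjusted p = 0.0959). Acta2, the smooth muscle actin of myofibroblasts, was 3.30 higher (adjusted p = 0.0752), and Myoc (-2.98, adjusted p = 0.062) and Smoc2 (-1.98, adjusted p = 0.0725), matrix genes of resting perimuscular fibroblasts, were lower. None of these genes but Cyp26b1 passed. In edgeR, 0 of 13553 genes were higher and 1 lower, 3481 had an unadjusted p under 0.05, and DESeq2 called 945.

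Interleukin-17 and inflammatory response genes had 0 of 29 past the threshold over all genes in PCL against saline, but 16 higher and 1 lower adjusted over the list alone (camera adjusted p = 8.53e-10; adjusted p = 0.386 with an estimated correlation). The other lists also had 0 over all genes. Adjusted over the list alone, cell cycle genes had 15 and 0 of 29 (adjusted p = 3.06e-11; adjusted p = 0.386 with an estimated correlation), contractile genes 8 and 1 of 18 (adjusted p = 1.21e-06; adjusted p = 0.386 with an estimated correlation) and collagen and matrix genes 10 and 2 of 37 (adjusted p = 1.87e-05; adjusted p = 0.386 with an estimated correlation). Resident perimuscular genes had 1 and 11 of 23 adjusted over the list alone (adjusted p = 7.59e-06; adjusted p = 0.386 with an estimated correlation), adventitial genes 1 and 11 of 17 (adjusted p = 1.87e-05; adjusted p = 0.386 with an estimated correlation), early-response genes 0 and 11 of 24 (adjusted p = 0.000456; adjusted p = 0.386 with an estimated correlation) and haemoglobin genes 0 and 4 of 4 (adjusted p = 0.00475; adjusted p = 0.386 with an estimated correlation). Senescence genes had 3 and 1 of 17 adjusted over the list alone (adjusted p = 0.0239 upward; adjusted p = 0.386 with an estimated correlation). Basement membrane (adjusted p = 0.0702), interferon (adjusted p = 0.442), TGF-beta target (adjusted p = 0.569) and tendon lists (adjusted p = 0.442, median -0.17 with a mean of 0.16) did not pass. Without the 1-week ECM, 1-week saline, 6-week ECM or 6-week PCL library 0 genes passed, without the 1-week PCL library 3, without the 6-week or 1-week naive library 199 or 212, and without the 6-week saline library 2278. Without both 1-week libraries labelled saline and naive the count was 284.

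Between fibroblasts labelled ECM and saline 0 genes passed the threshold. Saa3 was 6.92 higher (adjusted p = 0.326), the monocyte attractant Ccl2 1.57 higher (adjusted p = 0.303) and Postn, a matrix protein of activated fibroblasts, 2.44 higher (adjusted p = 0.339), at 3250 against 511 CPM. Hmcn2, a matrix protein of resting fibroblasts, was lower (-1.73, adjusted p = 0.303). None of these genes passed. In edgeR 0 genes passed, 1765 had an unadjusted p under 0.05, and DESeq2 called 107. Over the list alone, interleukin-17 and inflammatory response genes had 14 higher and 0 lower of 29 (adjusted p = 2.37e-12; adjusted p = 0.429 with an estimated correlation), contractile genes 3 and 0 of 18 (adjusted p = 3.45e-05; adjusted p = 0.57 with an estimated correlation) and resident perimuscular genes 2 and 7 of 23 (adjusted p = 0.00141; adjusted p = 0.57 with an estimated correlation), each count adjusted over the list alone. With 0 genes called adjusted over the list alone, the cell cycle (adjusted p = 0.000223) and collagen lists (adjusted p = 0.000773) leaned up and the early-response (adjusted p = 0.000396), basement membrane and interferon lists (adjusted p = 0.00265 for both) leaned down; each had adjusted p = 0.57 with an estimated correlation. The adventitial (adjusted p = 0.056), senescence (adjusted p = 0.0707), haemoglobin (adjusted p = 0.156), TGF-beta target (adjusted p = 0.336) and tendon lists (adjusted p = 0.587, median -0.23 with a mean of 0.19) did not pass. The count was 1 without the 1-week or 6-week ECM library, 2 without either naive or either PCL library, and 529 without the 6-week saline library. It was 22 without both 1-week libraries labelled saline and naive.

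Between the materials 0 genes passed in fibroblasts, and the interleukin-17 list was split (16 positive and 13 negative of 29, median 0.11). Saa3 was 3.18 higher (adjusted p = 0.622) and Timp1 1.94 higher (adjusted p = 0.689), while Myoc was at -1.38 and the glucocorticoid-activating enzyme gene Hsd11b1 at -2.29 (adjusted p = 0.622 for both). None passed. In edgeR 0 genes passed, 1006 had an unadjusted p under 0.05, and DESeq2 called 30. Over the list alone, 1 interleukin-17 gene was called (adjusted over the list alone; adjusted p = 0.0654 for the list). Cell cycle (adjusted p = 4.31e-10), contractile (adjusted p = 0.00578), collagen (adjusted p = 0.00847) and interferon lists (adjusted p = 0.0327) leaned up in PCL and adventitial (adjusted p = 8.05e-06), resident perimuscular (adjusted p = 0.000995) and haemoglobin lists (adjusted p = 0.00578) down; each had adjusted p = 0.665 with an estimated correlation. The senescence (adjusted p = 0.171), early-response (adjusted p = 0.236), basement membrane and tendon (adjusted p = 0.604 for both) and TGF-beta target lists (adjusted p = 0.755) did not pass, and the means of the latter pair were -0.02 and -0.04 with medians of 0.04 and 0.05. Without the 1-week ECM library 1 gene passed, and without either saline library 6. Without both 1-week libraries labelled saline and naive 256 passed.

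Between fibroblasts labelled saline and naive 0 genes passed the threshold. The median of the contractile list was -1.17 at 1 week and 0.02 at 6 weeks, and that of the collagen list -0.80 and 0.22, differences that were not tested. Acta2 was at 14.8 CPM in saline and 84.1 CPM in naive (log2 -1.82, adjusted p = 0.993), while the heat-shock gene Hspa1a, induced by cell stress, was 1.18 higher (adjusted p = 0.993). Neither passed. In edgeR 0 genes passed, 395 had an unadjusted p under 0.05, and DESeq2 called 1. The contractile list had 0 higher and 1 lower of 18 adjusted over the list alone (adjusted p = 1.91e-07; adjusted p = 0.684 with an estimated correlation). Cell cycle (adjusted p = 1.99e-07), collagen (adjusted p = 0.000268) and tendon lists (adjusted p = 0.0085) leaned down in saline and interferon (adjusted p = 2.33e-06), early-response (adjusted p = 1.36e-05) and adventitial lists (adjusted p = 0.000772) up; each had adjusted p = 0.684 with an estimated correlation. The resident perimuscular (adjusted p = 0.0877), interleukin-17 (adjusted p = 0.365), senescence (adjusted p = 0.423), TGF-beta target (adjusted p = 0.709, median 0.07 with a mean of -0.11), basement membrane (adjusted p = 0.84) and haemoglobin lists (adjusted p = 0.864) did not pass. Without the 6-week naive library 1 gene passed, and without the 6-week saline library 7. Leaving out both 1-week libraries labelled saline and naive gave 8.

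**Figure D3:**
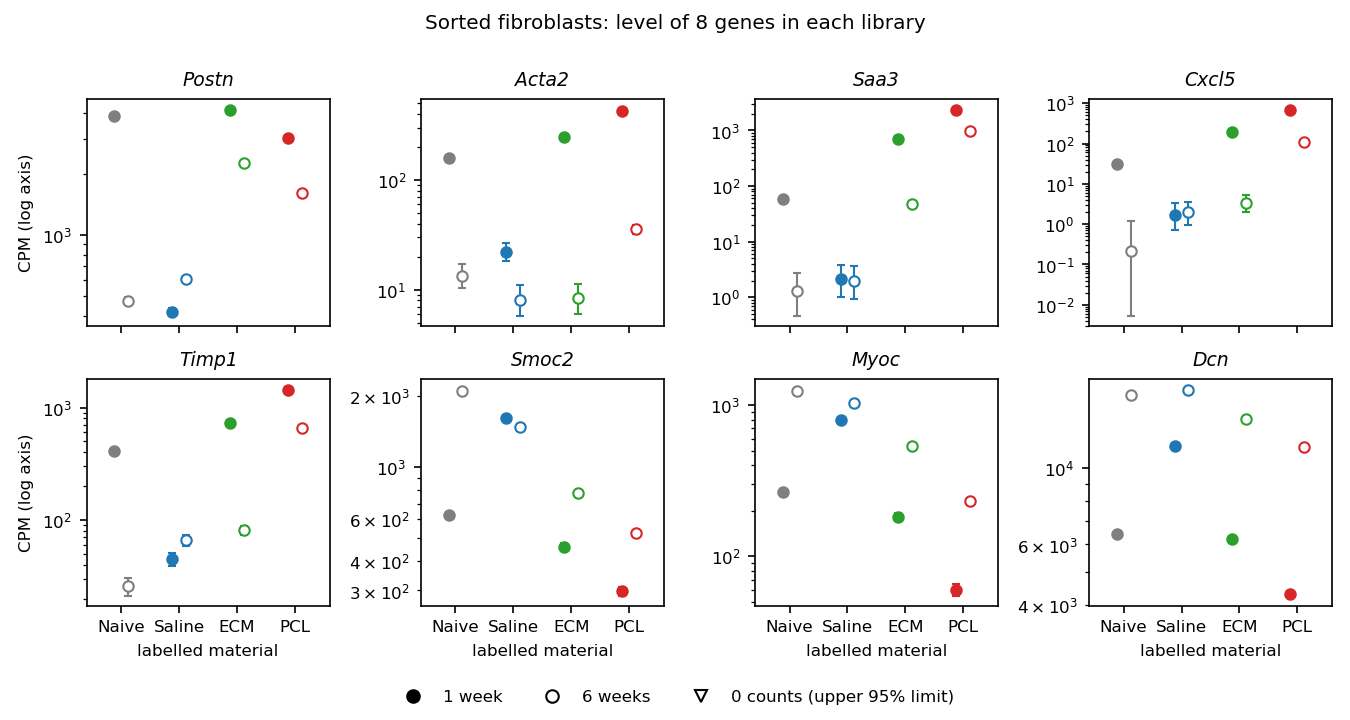
CPM (log axis) of 8 genes in fibroblast-like cells of the fibroblast sort by labelled material, filled circles for 1 week and open circles for 6 weeks, 1 library each, with 95% counting intervals as bars. Saa3 is at 2380 (1 week) and 993 (6 weeks) in PCL and 2.09 and 1.97 in saline, and Acta2 at 159 and 13.4 in naive and 22.2 and 8.07 in saline.

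From 1 to 6 weeks, 16 of 29 cell cycle and 8 of 18 contractile genes fell in fibroblasts, and 4 of 17 adventitial and 4 of 23 resident perimuscular genes rose. Acta2 fell by 3.43 (SE 0.48, adjusted p = 0.0133), Mki67, present in dividing cells, by 2.84 (adjusted p = 0.0214), and Tnn, a tenascin of healing matrix, by 4.77 (adjusted p = 0.0133). Cxcl5 fell by 3.71 (adjusted p = 0.0349). Dcn, the abundant collagen-binding proteoglycan, rose by 1.16 (adjusted p = 0.0173), from 7010 to 14800 CPM, Myoc by 1.58 (adjusted p = 0.0245) and the glucocorticoid-induced Tsc22d3 by 1.73 (adjusted p = 0.00553). The cell cycle inhibitor gene Cdkn1a rose by 1.23 (adjusted p = 0.0183). These directions held in all 4 materials but for Cxcl5, and for Tnn, Mki67 and Cxcl5 the change in the pair labelled saline was -0.01, -0.43 and 0.24. The pair labelled naive, set apart from the surgery groups, is part of this fit and changed as well. Without TMM factors, Acta2 went from 159 to 13.4 CPM in naive and from 22.2 to 8.07 CPM in saline. Postn went from 3860 to 474 CPM in naive and from 418 to 609 CPM in saline. So the comparison is not time after surgery alone, and a possible exchange of the 1-week saline and naive labels bears on it. In edgeR, 598 genes were higher and 737 lower, 4079 had an unadjusted p under 0.05, and DESeq2 called 1663. All 1335 had the same sign in at least 3 of the 4 materials.

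Cell cycle genes had 0 higher and 16 lower of 29 at 6 weeks (0 and 26 adjusted over the list alone, adjusted p = 3.88e-16; adjusted p = 0.52 with an estimated correlation), and contractile genes 0 and 8 of 18 (0 and 12 adjusted over the list alone, adjusted p = 5.12e-08; adjusted p = 0.52 with an estimated correlation). Early-response genes had 13 and 0 of 24 (18 and 0 adjusted over the list alone, adjusted p = 1.75e-08; adjusted p = 0.52 with an estimated correlation), adventitial genes 4 and 0 of 17 (8 and 0 adjusted over the list alone, adjusted p = 2.61e-05; adjusted p = 0.678 with an estimated correlation) and resident perimuscular genes 4 and 0 of 23 (6 and 0 adjusted over the list alone, adjusted p = 0.000132; adjusted p = 0.52 with an estimated correlation). Collagen genes went both ways (2 and 2 of 37, adjusted p = 0.134), with the crosslinking enzyme gene Loxl2 at -0.92 against Dcn, and so did interleukin-17 genes (2 and 3 of 29, adjusted p = 0.564) and senescence genes (3 and 1 of 17, adjusted p = 0.147). Basement membrane (0 of 13, adjusted p = 0.511), interferon (0 of 26, adjusted p = 0.511), TGF-beta target (1 and 1 of 21, adjusted p = 0.564), tendon (1 and 1 of 20, adjusted p = 0.36) and haemoglobin genes (0 of 4, adjusted p = 0.828) did not pass. Without 1 library the count was 24 (1-week ECM), 44 (6-week ECM), 81 (1-week PCL), 88 (6-week PCL), 271 (1-week naive), 274 (6-week naive), 3145 (1-week saline) or 3151 (6-week saline), and 2802 without both 1-week libraries labelled saline and naive.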

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

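The tests of cell depth and of cells of another type and the set of splits were chosen after the result was seen, and the other tests in this part were written before. No group held 4 to 10 replicate samples, so no library was tested as standing apart from its group.

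Several values pointed one way in one age or time and the other way in the other, with 1 library per arm, and these differences were not tested. The median log2 change of interferon genes in macrophage-like cells was -0.97 in young and 0.55 in old mice for ECM against saline, and 0.71 and -1.39 for PCL against ECM. In sorted fibroblasts, tendon and cartilage genes were at 0.81 at 1 week and -0.67 at 6 weeks for PCL against saline, and at 0.63 and -0.71 for ECM against saline. Haemoglobin genes in fibroblasts were at -1.48 at 1 week and 1.27 at 6 weeks for saline against naive. The share of macrophage-like cells differed by 4.0 points in young and -14.0 points in old mice for PCL against saline, and by -30.0 and 4.1 points for saline against naive. The macrophage-sort library labelled PCL held 2.4% neutrophil-like cells, a signal in cells that no comparison used, where the other libraries of that sort held 0 (limits of 0.132% in ECM and 0.88% in saline).

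The CD45-enriched libraries labelled naive held fibroblast-like cells with an activated profile and those labelled ECM a resting one. The depth of the cells cannot account for this. Among cells of 500 to 1000, 1000 to 2000 or 2000 to 4000 UMIs, the correlation with 6-week naive minus that with 1-week ECM sorted fibroblasts was 0.066 to 0.104 in the libraries labelled ECM and -0.145 to -0.042 in those labelled naive, and the smallest gap was 0.124. Over all depths, the library labelled ECM correlated more with 6-week naive than with 1-week ECM fibroblasts, by 0.103 in young (0.088 to 0.118) and 0.086 in old mice, while the other young libraries gave -0.146 to -0.185. Macrophage-like cells of the young library labelled saline correlated more with the macrophage-sort library labelled PCL than with that labelled saline, by 0.058 (0.048 to 0.069; old 0.038), against -0.039, -0.081 and -0.022 for young PCL, ECM and naive. A candidate explanation is that material labels were assigned to the wrong CD45-enriched libraries, which may mean that the named contrasts in macrophage-like cells compare other materials; a difference between animals stays open as well, since each label and age is 1 library, and no biological explanation was tested.

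The 1-week fibroblast library labelled saline stood close to the 6-week library labelled naive, and that labelled naive close to 1-week ECM. Markers of macrophages, neutrophils, endothelial, muscle fibre, pericyte, satellite and Schwann cells were in small net excess. Over all cells, the excess of these 72 markers in naive over saline was 337 CPM, which is 1.74% of the 19400 CPM excess of Postn, Cthrc1, Tnc and Col3a1. Muscle fibre-like cells were 2.06% in naive and 0.74% in saline, and satellite cell-like cells 4.75% and 6.83%. Such shifts can offset each other in a net excess, so it does not exclude each type singly. The library labelled saline correlated more with the 6-week naive library than that labelled naive did, by 0.078 (0.069 to 0.088), and less with 1-week ECM, by 0.082 (0.073 to 0.092). The values are consistent with an exchange of these 2 labels, which would place the saline and naive contrasts of fibroblasts at 1 week on the wrong libraries. Tenocytes (marker excess 544 CPM, with a tenocyte-like share of 1.77% in naive and 4.37% in saline) and a difference between animals stay open, since each label is 1 library, and no biological explanation was tested.

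For age in macrophage-like cells, 8 splits of the 8 libraries put 1 library of each material on each side, which is too few for a share under 0.05. The real split gave 1477 genes and the highest other 140, so 1 of the 8 gave as many. For harvest time in fibroblasts the 8 such splits are too few as well, and the real split gave 1335 genes against 0 for the highest other.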

How the results depend on the processing

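The settings chosen after the data were seen were leaving out the 5% of cells with the highest scrublet score, adding monocyte-like cells, and leaving out the 1-week fibroblast libraries labelled saline and naive; all others were planned. Over all settings, counts and medians stayed within 1.5 times or their interval in 136 of the cases and moved in 79, and shares in 60 and 16. Named genes kept direction and call in 5527 cases, lost the call in 1039, gained it in 124 and reversed in 11. Many of these cases come from settings that altered the fit little. RLE factors kept 347, and removal of scrublet calls kept 345 and lost 2. With the macrophage-sort libraries as a block, 121 lost the call and 5 reversed. With no block for age 66 kept the call and 107 lost it. With all cells summed 191 kept it, 153 lost it and 3 reversed. Macrophage-sort ratios stayed in 321 cases and moved in 16. Where a result changed, the cause was not tested, except that fewer libraries or genes enter some fits. Depth limits genes near 1 UMI in the 74 macrophage-like cells of young ECM.

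With 1 library left out, counts ran from 232 to 571 (PCL against saline), 283 to 1159 (ECM against saline), 24 to 187 (PCL against ECM), 161 to 773 (saline against naive) and 498 to 1773 (old against young) in macrophage-like cells. In fibroblasts they ran from 0 to 2278, 0 to 529, 0 to 6 and 0 to 7 for the same pairs of materials and from 24 to 3151 for harvest time. A lone library of a material is then assumed to vary like the others.

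In macrophage-like cells, PCL against saline gave 313 genes with DESeq2, 31 with no block for age, 26 with all cells summed and 0 with the macrophage-sort libraries added as a block (153 at an unadjusted p under 0.05). ECM against saline gave 232 with no block for age, 377 with all cells summed and 0 with the sort added (705 unadjusted). PCL against ECM gave 5, 19 and 0 (328 unadjusted) for the same 3 settings. Saline against naive gave 246 with DESeq2, 35 with no block for age and 37 with all cells summed, and old against young 972 with DESeq2 and 325 with no material block. In fibroblasts DESeq2 gave 945, 107, 30 and 1 for the pairs of materials. With no filter on low counts PCL against saline gave 136 and ECM against saline 1. PCL against saline gave 0 with no block for harvest time (1595 unadjusted) and 0 with all cells summed (3579 unadjusted). Without the 1-week libraries labelled saline and naive the counts were 284, 22, 256, 8 and, for harvest time, 2802; with no material block harvest time gave 454.

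Genes that reversed were C4b (-0.64, all cells summed), Chil3 (0.29) and Egln3 (1.10, both with the sort added) in ECM against saline; Ndrg1 (-0.31) and Tgm2 (-0.35, both all cells summed), Saa3 (-0.56, with the sort added) and Hp (-0.37, monocyte-like cells added) in PCL against ECM; H2-DMb2 (-0.60) and Jun (-0.15, both with the sort added) and Ccl8 (-0.14 without young PCL to 3.40 without old PCL) in PCL against saline. In fibroblasts Cthrc1 ran from -0.05 without 1-week saline to 6.65 without 6-week saline in ECM against saline. The median macrophage-like share was 40.3% in cells with at least 500 genes and 39.6% at resolution 2, both higher than with the settings used. At 20 CPM the macrophage sort had 495, 577 and 523 genes at 2-fold (PCL against saline, ECM against saline, PCL against ECM), against 280, 333 and 312. With an estimated correlation, 0 gene list tests passed.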

Other observations

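Dendritic cell-like cells, which present antigen to T cells, were 10.0% of the old CD45-enriched library labelled ECM and 1.44% of the young one. Mast cell or basophil-like cells, a source of type 2 cytokines, were 1.76% of young PCL and 0.25% to 0.95% of the others. Gata3, the type 2 lineage factor, had a UMI in 17.4% of T or NK cell-like cells of young PCL, against 0.30% of its macrophage-like cells, and in 7 of 34 of young ECM, against 0 of 74 macrophage-like cells. Gata3 is also a marker used to name the T or NK cell-like class, so this gap is partly built in. These shares are from single libraries and were not tested.

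In the fibroblast sort, tenocyte-like cells, which make tendon matrix, were 8.09% of 6-week saline and 0.60% of 1-week PCL. Muscle satellite cell-like cells, the stem cells of muscle, ran from 0.88% in 6-week PCL to 6.83% in 1-week saline, and pericyte or smooth muscle-like cells from 2.39% in 6-week ECM to 7.44% in 1-week PCL. In the same sort, a cluster led by Cxcl9, Cxcl10, Apoe, Fgf10 and Iigp1 held 9.96% of cells in 6-week ECM and 3.91% to 6.63% in the other libraries. Of these genes Cxcl9, Cxcl10 and Iigp1 are induced by interferon gamma.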
